A study of Mus musculus with 4 samples.

How the data were processed

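Ribosome profiling sequences the short mRNA pieces that ribosomes protect, so that a gene's read number follows how many ribosomes sat on its transcripts. The 4 libraries were ribosome footprints from dorsal root ganglia, which hold the cell bodies of sensory neurons, of female wild-type SW mice. Per the labels' protocols, the mice received paclitaxel, a microtubule-stabilising chemotherapy drug that causes peripheral neuropathy, at 4 mg/kg into the peritoneum in 4 injections on alternate days. Per the labels' protocols, ribosome-bound RNA was isolated on size-exclusion spin columns, ribosomal RNA was depleted with a hybridisation kit, footprints of 28 to 34 nt were cut from a gel, and libraries were made with a small-RNA kit. The same labels mention 3′ mRNA sequencing for RNA abundance. RNA libraries and libraries of untreated mice were not analysed here, so no translational efficiency was computed and no value is an effect of paclitaxel.

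The submitters' processing notes name FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1, with the genome builds GRCm38.p4 and mm10, without their roles. The counting rule, the treatment of reads that match several places, the annotation release and the normalisation were not given in the sources used here. The deposited table has 1 column per library and 48431 genes, and it is named as holding TPM. In the deposited columns 96.5% to 96.8% of the values above 0 were whole multiples, within 0.05, of 1 step shared by genes of all lengths, and each column summed to 1000000. The values that the authors deposited were therefore used as CPM, a gene's reads scaled to a library total of 1000000, with no correction for gene length. The step was the value of 1 read and gave depths of 5731506, 9255057, 14633422 and 10424947 assigned reads in replicates 1 to 4. A gene with no read could lie at up to 3 reads, which is 0.523, 0.324, 0.205 and 0.288 CPM in the same order. Intervals for single libraries are 95% Wilson intervals on reads, and intervals and floors cover counting error only. No pair of libraries held identical values, and the median chi-square per gene between 2 libraries was 1.54 to 2.22, so all 4 were counted as separate replicates.

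The tests were planned for TPM, and the same tests were run on log2(CPM + 1). Because CPM grows with gene length, CPM per kilobase of the longest annotated coding sequence was added after the data were examined and the log2 values that it turns are given. Gene identifiers were matched to GENCODE M21 on GRCm38, which gave 48052 matches, with 379 identifiers left without one and 22243 genes with a coding length. Coordinates are GRCm38, counted from 1. The share of each coding sequence's 30-nt words found in no transcript of another annotated gene, on either strand, was computed as the unique share, also after the data were examined. Copies outside annotated transcripts were not searched.

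A gene was called detected at 1 CPM or more in all 4 libraries. Each of 42 gene lists fixed before the data were examined was summarised per library as the median log2(CPM + 1) of its members minus the median over all detected genes. List levels and 14 list pairs were tested with a 2-sided exact sign-flip permutation test over the 4 libraries, whose smallest possible p is 0.125, with Benjamini-Hochberg adjustment. The log2 ratios of 45 gene pairs were tested against 0 with limma 3.58.1 and adjusted over the 45 pairs. Genes with a mean of at least 1 CPM were tested for a between-library variance above that of genes of the same level, with limma's trended and robust prior variance, an F test and adjustment over all genes. Lists rich in such genes were found with a 1-sided Fisher's exact test, adjusted over lists. Counts adjusted over a list alone were not planned and are not corrected across lists. The adjusted p threshold was 0.05. The labels do not say whether the replicates were separate animals, so p-values measure only the spread between these libraries. On simulated libraries of the same depths the variance test recovered 56% of 2-fold and 98% of 4-fold changed genes with 3 false calls among 15721 genes. The pair test recovered all simulated 2-fold ratios in 22 of 45 pairs and made 2 false calls, 8.33% of its calls. Both simulations gave all genes the same dispersion of 0.01. The false calls may therefore not hold for real genes of equal level that differ in variance.

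Named genes followed a rule fixed before the data were examined. The rule took the 15 genes with the highest mean, up to 4 detected members with the highest mean and the undetected members of each list, all gene pairs, all noncoding and Y-linked list members, and the 20 variable genes with the smallest p. Some of these genes and pairs are not reported here, though they were kept in all lists, counts and adjustments. Alternatives were a pseudocount of 0.1, rescaling without mitochondrial genes and the 20 highest genes, quantile normalisation, leaving out each library in turn, means over list members, other level filters, limma with trend, and a variance test without the robust prior. Added after the data were examined were coding length, protein-coding genes only and a unique share of at least 90%. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.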

Results

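Ribosome footprints were measured in dorsal root ganglia of female mice given paclitaxel, in 1 group of 4 libraries. The series concerns translation in paclitaxel-induced neuropathy. With 1 group, the values describe which transcripts had reads in footprint libraries of the treated ganglia and how far the 4 libraries differed. Whether each read came from a ribosome was not checked, and RNAs that are not translated had reads too. Untreated mice were not analysed here, so no level is an effect of the drug. Values are means ± SD over n = 4 libraries, in CPM unless stated otherwise, at depths of 5731506 to 14633422 assigned reads. Folds are on the log2(CPM + 1) scale, which understates them for low genes.

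Reads were detected on 14726 genes, of which 13549 were protein coding and 1177 were not annotated as such. The mRNA with the highest mean level was Map1b (ENSMUSG00000052727.5, chromosome 13, 99421446 to 99516540, minus strand), which encodes a microtubule-associated protein of axons, at 10799 ± 1279 CPM. It was followed by Lars2, the mitochondrial leucyl-tRNA synthetase, at 9418 ± 4275 CPM, which was above Map1b in replicates 3 and 4. Whether the Lars2 reads came from its coding sequence was not checked. Other leading mRNAs were Apoe (6502 ± 522 CPM), Col1a1 (5330.3 ± 1539 CPM) and the neurofilament genes Nefl (5109.7 ± 542 CPM) and Nefm (4701 ± 615 CPM). Pmp22 (4489 ± 879.7 CPM), Hsp90ab1 (4350.2 ± 159.6 CPM), Prune2 (3974 ± 187 CPM) and Apod (3657 ± 307 CPM) were also among the 15 highest genes, as was the annotated ribosomal RNA gene Gm24601 at 3748 ± 1888 CPM. Mitochondrial ribosomal RNA remained in the libraries. The mt-Rnr1 values were 3658, 6872, 14530.3 and 12879 CPM in replicates 1 to 4, and the mt-Rnr2 values were 23520.5, 61455, 0 and 52082 CPM, so that mt-Rnr2 was listed at 0 in replicate 3 alone.

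The 4 libraries ranked genes much alike. Pearson's r of log2(CPM + 1) lay between 0.973 and 0.982 and Spearman's rho between 0.975 and 0.984 for the pairs of libraries, across 15728 genes, which are not independent replicates. The median coefficient of variation was 14.0% over these genes, 26.3% for genes at 1 to 5 CPM and 8.57% for genes at 100 to 1000 CPM. Protein-coding genes took 93.4%, 89.2%, 94.5% and 89.0% of reads in replicates 1 to 4. No mt-Rnr2 reads were counted in replicate 3, which raises the share of all other genes there. From the lowest mt-Rnr2 to mt-Rnr1 ratio elsewhere, these reads would make up 5.55% of that library. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were all undetected, with a summed level of 0.820 ± 0.343 CPM, and Xist, the X-inactivation RNA of females, stood at 4.01 ± 0.477 CPM. The labels give female mice.

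Neuronal transcripts had many reads. All 10 pan-neuronal genes were detected, with a list median of 626 ± 40.2 CPM, which was 4.95 ± 0.15 above the median gene on the log2 scale. Tubb3, the neuronal beta-tubulin, stood at 2939 ± 81.0 CPM, Uchl1 at 2436 ± 317 CPM, Stmn2 at 862 ± 102 CPM and Snap25 at 824 ± 109.5 CPM. Across all 42 lists, 28 lay above the median gene in 4 of 4 libraries and the others lay below it in 4 of 4. Each of these list levels had an exact sign-flip permutation p of 0.125 (adjusted 0.125), the smallest that 4 libraries allow, so no list level could pass 0.05.

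Among sensory neuron classes, genes of non-peptidergic nociceptors had the highest median, followed by those of myelinated afferents and of peptidergic nociceptors. The medians were 235 ± 35.8, 197 ± 13.5 and 106 ± 8.89 CPM, and all 7, 7 and 6 members were detected. The non-peptidergic list was led by the receptor gene Ret (ENSMUSG00000030110.13, chromosome 6, 118151745 to 118197718, minus strand) at 744 ± 44.7 CPM, the purinergic channel P2rx3 at 334 ± 28.8 CPM and the itch and pain receptor Mrgprd at 322 ± 35.1 CPM. In the peptidergic list Calca (ENSMUSG00000030669.13, chromosome 7, 114631478 to 114636357, minus strand), which encodes the neuropeptide CGRP, reached 714 ± 74.9 CPM and Tac1, the substance P gene, 107 ± 21.3 CPM. Nefh at 2700.0 ± 311 CPM and Cntnap2 at 279.6 ± 30.4 CPM led the myelinated afferents. Itch neuron genes had a median of 22.3 ± 2.15 CPM, with Osmr at 83.3 ± 2.13 CPM, and the C-fibre low-threshold mechanoreceptor genes one of 10.7 ± 2.54 CPM, with Th at 131 ± 24.3 CPM. The latter list lay −0.81 ± 0.25 from the median gene, and 0.75 ± 0.26 per kilobase.

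The peptidergic median was lower than the non-peptidergic one by a log2 difference of −1.14 ± 0.29, in 4 of 4 libraries, and by −0.35 ± 0.29 per kilobase of coding sequence. Against myelinated afferents the peptidergic median differed by −0.90 ± 0.14, and per kilobase this turned to 0.82 ± 0.12. Every list pair but 1 had an exact permutation p of 0.125 (adjusted 0.135), which cannot reach 0.05 with 4 libraries. The exception was myelinating Schwann cell against satellite glia genes, with a difference of −0.17 ± 0.36, higher in 2 of 4 libraries (exact permutation p = 0.5), and 0.34 ± 0.42 per kilobase. This difference was −0.44 after rescaling without mitochondrial genes and the 20 highest genes, but 0.56 with means over members (exact permutation p = 0.125 for each).

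**Figure D1:**
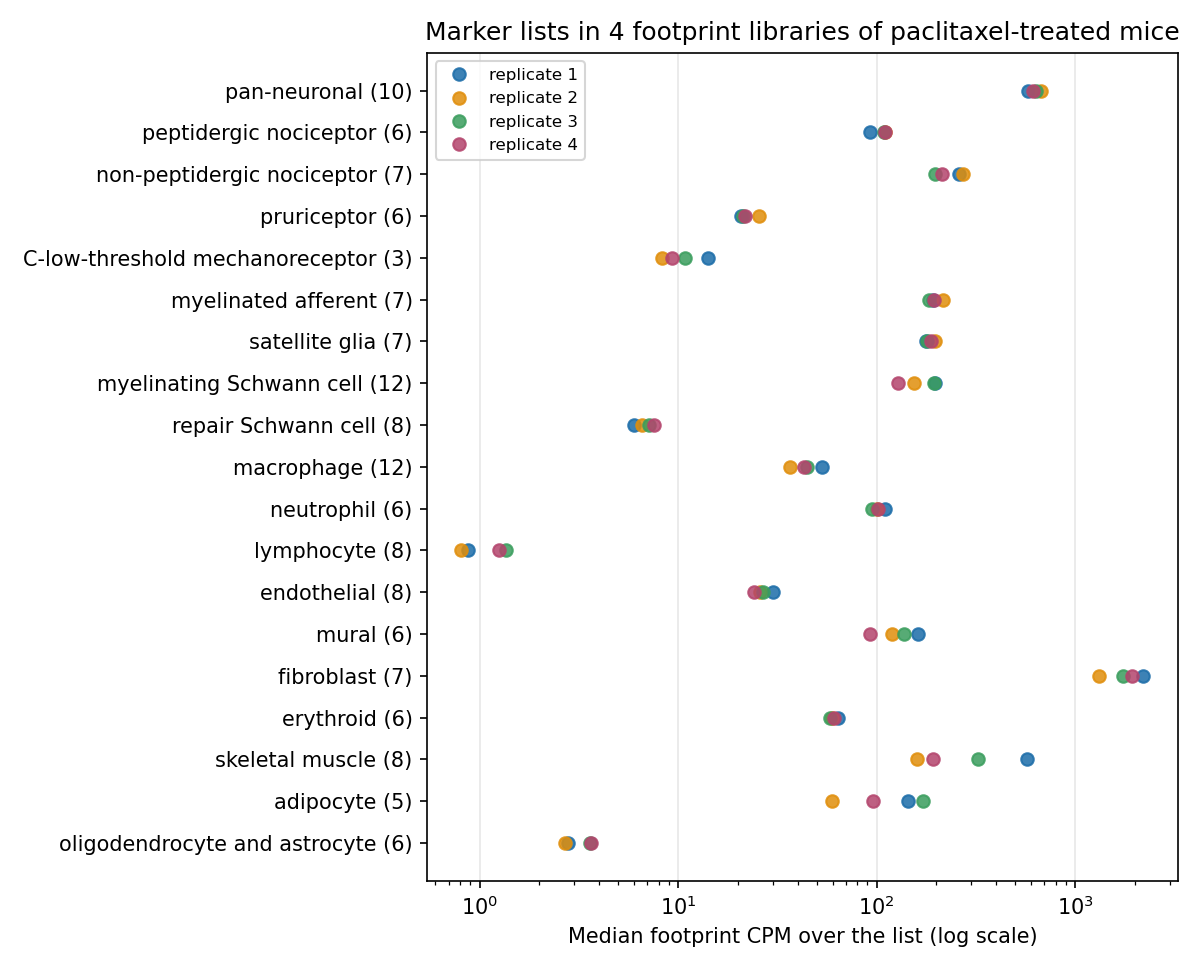
Median footprint level (CPM, log axis) of 19 cell type marker lists, with the number of measured members in brackets and 1 point per library. Fibroblast and pan-neuronal lists had the highest medians, at 1804 ± 374 and 626 ± 40.2 CPM, and the skeletal muscle points spread from 161 CPM in replicate 2 to 574 CPM in replicate 1.

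Glial transcripts were led by myelin genes. The 12 myelinating Schwann cell genes were all detected and summed to 17562 ± 3674 CPM, with Pmp22 and, at 2588 ± 591 CPM, Mbp among the highest. The repair Schwann cell list, which marks Schwann cells after nerve injury, had 5 of 8 members detected. Its highest members were Ngfr, the p75 neurotrophin receptor, at 363 ± 22.3 CPM, Gfap at 41.4 ± 13.9 CPM and Sox2 at 13.9 ± 1.08 CPM, while Gdnf, Artn and Btc were not detected. Myelinating genes were 26.9-fold above repair genes by list median (log2 4.75 ± 0.38) and 40.2-fold above oligodendrocyte and astrocyte genes (5.33 ± 0.39), in 4 of 4 libraries. In the latter list Olig2 and Opalin were not detected, and Aqp4 was at 10.9 ± 3.11 CPM. Satellite glia, which wrap neuronal cell bodies, showed Apoe (ENSMUSG00000002985.16, chromosome 7, 19696109 to 19699188, minus strand), Glul at 305 ± 32.9 CPM, Fabp7 at 254 ± 54.6 CPM and Gja1 at 179 ± 21.2 CPM. The pan-neuronal median was 3.33-fold above that of satellite glia (1.73 ± 0.07).

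Immune, vascular and connective tissue genes were present too. All 12 macrophage genes were detected, led by Lyz2 (191 ± 34.6 CPM), Csf1r (119 ± 20.3 CPM) and Mrc1 (115 ± 18.0 CPM). Of 8 lymphocyte genes 3 were detected, Cd79a at 4.48 ± 1.38 CPM, Cd4 at 3.41 ± 2.79 CPM and Ms4a1 at 2.30 ± 0.380 CPM, and the T-cell genes Cd3e, Cd3d, Cd3g and Cd8a were not. The macrophage median was 21.8-fold above the lymphocyte median (4.45 ± 0.27) but below the neutrophil median (−1.08 ± 0.17), and per kilobase these differences were 3.69 ± 0.10 and −2.62 ± 0.09. The 6 neutrophil genes included S100a9 at 317 ± 25.2 CPM, S100a8 at 196 ± 13.1 CPM and Ngp at 141 ± 12.0 CPM. Erythroid genes included Hba-a1 at 410.1 ± 53.1 CPM, whose coding sequence was 28.2% unique, and Slc4a1 at 80.2 ± 6.27 CPM; Hba-a2 was not detected. Fibroblast genes had a median of 1804 ± 374 CPM, with Col1a2 at 3645 ± 1011 CPM and Dcn at 2416 ± 267 CPM beside Col1a1. Endothelial genes had a median of 26.7 ± 2.52 CPM, with Cdh5 at 121 ± 14.9 CPM, and mural cell genes one of 128 ± 29.5 CPM, with Cspg4 at 166 ± 26.8 CPM. Adipocyte genes had a median of 118 ± 50.0 CPM, and skeletal muscle genes of 313 ± 188 CPM.

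The sensory neuron sodium channels Scn11a and Scn10a (ENSMUSG00000034533.9, chromosome 9, 119608456 to 119719322, minus strand), which encode Nav1.9 and Nav1.8, stood at 1488 ± 192 and 1181 ± 111 CPM. Scn9a, which encodes Nav1.7, was at 384 ± 25.9 CPM, 3.07-fold below Scn10a (log2 −1.62 ± 0.11; limma adjusted p = 3.5e-11). Scn10a was below Scn11a by a small margin (−0.33 ± 0.07; limma adjusted p = 0.0011), and Scn8a was 2.93-fold above Scn1a. All 13 sodium, 15 calcium and 13 potassium and HCN channel genes measured were detected, with medians of 65.3 ± 10.7, 50.8 ± 2.83 and 48.1 ± 4.10 CPM. These lists lay 1.71 ± 0.23, 1.37 ± 0.11 and 1.29 ± 0.06 from the median gene on the log2 scale, and 1.91 ± 0.08, −0.14 ± 0.13 and 0.29 ± 0.06 per kilobase. The sodium minus calcium channel difference was 0.34 ± 0.22, and 2.05 ± 0.06 per kilobase. Cacna2d1, which encodes a gabapentin-binding subunit, at 204 ± 9.55 CPM was 1.93-fold above Cacna2d2 and 3.80-fold above Cacna2d3. Kcna1 at 259.6 ± 31.6 CPM led the potassium channels.

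All 14 transduction channel genes were detected. The touch channel Piezo2 reached 619 ± 47.9 CPM, 28.5-fold above Piezo1 (log2 4.84 ± 0.30; limma adjusted p = 2.3e-15). Trpv1, the capsaicin receptor, at 101 ± 5.32 CPM was above the cold receptor Trpm8 (log2 0.59 ± 0.13) and 1.16-fold above Trpa1. The latter call (limma adjusted p = 0.023) was lost when replicate 1, 2 or 3 was left out, with limma adjusted p of 0.078, 0.094 and 0.081. Asic3 was at 109 ± 22.5 CPM.

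Ret was the highest of the neurotrophic factor receptor genes, and Ntrk2 stood at 226 ± 10.8 CPM. The GDNF family receptor Gfra2 was 2.36-fold above Gfra1 and 3.61-fold above Gfra3. Calca was 8.07-fold above Calcb and 6.67-fold above Tac1. Of 14 neuropeptide genes 11 were detected, with Nmb at 106 ± 6.63 CPM, and Pomc, Pdyn and Vip were not; the list median lay −0.35 ± 0.19 from the median gene but 1.40 ± 0.22 per kilobase. The mu opioid receptor gene Oprm1, at 53.5 ± 11.7 CPM, was 5.81-fold above the delta receptor gene Oprd1. The cannabinoid receptor gene Cnr1, at 26.6 ± 3.10 CPM, was 13.2-fold above Cnr2, and Cnr2 did not reach 1 CPM in all 4 libraries.

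**Figure D2:**
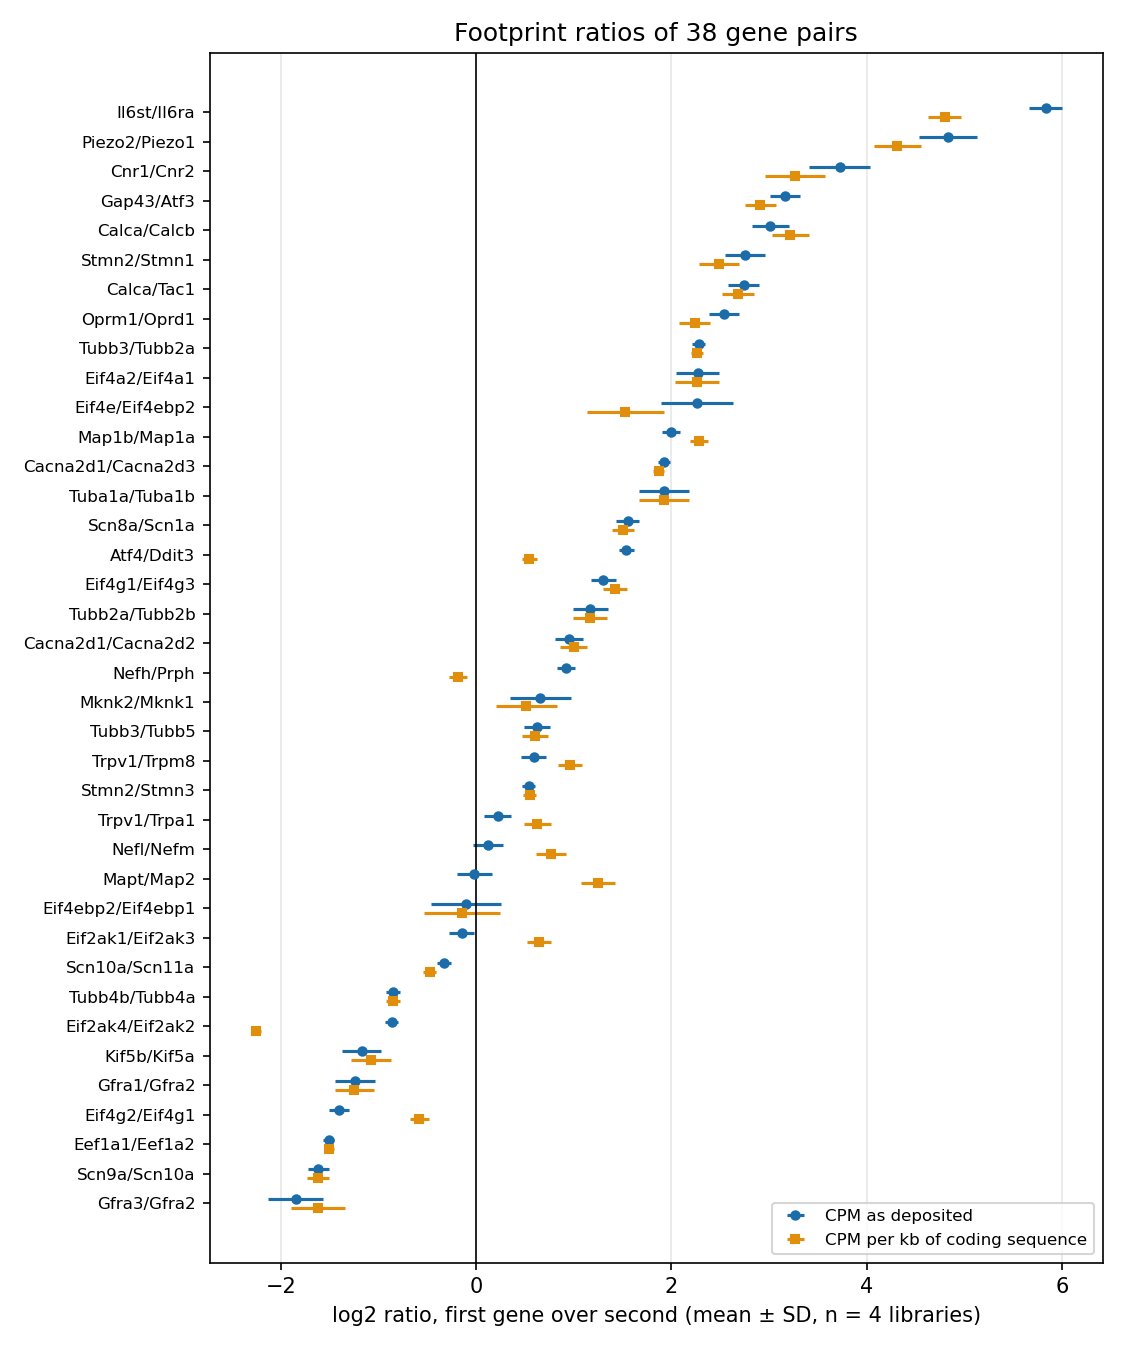
Log2 footprint ratio of the first over the second gene for 38 of the 45 fixed pairs (points, mean; bars, SD; n = 4 libraries), from CPM as deposited and from CPM per kilobase of coding sequence. Il6st over Il6ra had the highest ratio, at 5.83 ± 0.17, and Nefh over Prph lay at 0.92 ± 0.09 from CPM and −0.19 ± 0.09 per kilobase.

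Cytoskeletal genes, which include the target of paclitaxel, were among the most abundant groups. Neurofilament genes had a median of 2700.0 ± 311 CPM and tubulin genes of 318 ± 4.71 CPM, an 8.55-fold difference (log2 3.10 ± 0.20) in 4 of 4 libraries. The log2 difference was 2.04 ± 0.10 per kilobase, and 2.18 after rescaling without mitochondrial genes and the 20 highest genes, which include Nefl and Nefm. Summed over members the gap was smaller, at 13966 ± 1416 CPM for the 5 neurofilament genes and 8283 ± 308 CPM for the 14 tubulin genes. Tubb3 (ENSMUSG00000062380.3, chromosome 8, 123411424 to 123422015, plus strand) was 1.54-fold above Tubb5, at 1912 ± 148 CPM, and 4.85-fold above Tubb2a (log2 2.28 ± 0.06; limma adjusted p = 2.8e-13). Tubb4a, at 758 ± 46.7 CPM, was 1.80-fold above Tubb4b, Tubb2a was 2.25-fold above Tubb2b, and Tuba1a was 3.80-fold above Tuba1b. These tubulin ratios and the level of the tubulin list are uncertain. The coding sequences of Tubb2a, Tubb2b, Tubb4b, Tuba1a and Tuba1b were only 43.1%, 53.7%, 34.6%, 30.2% and 13.8% unique. Map1b was 3.98-fold above Map1a, Stmn2 was 6.72-fold above Stmn1, and the neuronal kinesin gene Kif5a, at 1296 ± 135 CPM, was 2.26-fold above Kif5b. Dync1h1, the dynein heavy chain gene, was at 3518 ± 403 CPM. Nefl and Nefm were not separated as CPM (0.12 ± 0.15; limma adjusted p = 0.17), nor were Mapt and Map2 (−0.02 ± 0.18; limma adjusted p = 0.81). Per kilobase, Nefl and Mapt were higher (0.77 ± 0.15 and 1.25 ± 0.18), and Nefh over Prph turned from 0.92 ± 0.09 to −0.19 ± 0.09 with limma adjusted p of 2.5e-08 and 0.033.

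Genes of nerve injury were low beside neuronal genes. The injury list had 10 of 15 members detected and a median of 7.38 ± 1.27 CPM, −1.27 ± 0.19 from the median gene and −6.22 ± 0.29 from the pan-neuronal median. Per kilobase these log2 differences were −0.49 ± 0.07 and −6.08 ± 0.06. Jun at 117 ± 9.30 CPM, the growth cone gene Gap43 at 73.5 ± 6.27 CPM, the peptide gene Gal at 29.7 ± 6.76 CPM and Csf1 at 26.2 ± 3.39 CPM were its highest members, and Sprr1a, Ecel1, Cckbr, Crh and Vip were not detected. Atf3, a transcription factor gene induced in injured neurons, was the median member at 7.38 ± 1.27 CPM, 8.95-fold below Gap43 (log2 of Gap43 over Atf3 3.16 ± 0.15; limma adjusted p = 2.4e-14).

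Several inflammatory mediators were near the floor. Of 18 inflammatory genes 9 were detected, among them the receptor genes Il6st (723 ± 60.8 CPM) and Tnfrsf1a (30.5 ± 5.30 CPM) and the chemokine gene Cx3cl1 (14.5 ± 1.92 CPM). The cytokine and chemokine genes Il1b, Il6, Tnf, Ccl3, Ccl4, Ccl5 and Cxcl1 stayed under 1 CPM in at least 1 library. Il10 and Cxcl2 had no read in any library, which allows up to 0.205 CPM in replicate 3 and 0.523 CPM in replicate 1. Il6st was 57.0-fold above Il6ra (log2 5.83 ± 0.17; limma adjusted p = 2.7e-17), and 27.8-fold per kilobase.

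Translation factor genes exceeded those of the stress response. All 19 were detected and had a median of 99.8 ± 7.78 CPM, and the stress response list, with 15 of 16 detected and Trib3 not, had 28.0 ± 1.74 CPM, a log2 difference of 1.80 ± 0.11. Eef1a2, the elongation factor form of neurons and muscle, at 1592 ± 69.6 CPM was 2.85-fold above Eef1a1 (−1.51 ± 0.06; limma adjusted p = 4.1e-11), whose coding sequence was 25.5% unique. Eif4a2 was 4.82-fold above Eif4a1 (32.4% unique), Eif4g1 was 2.65-fold above Eif4g2 (log2 of Eif4g2 over Eif4g1 −1.41 ± 0.10, per kilobase −0.58 ± 0.10) and 2.47-fold above Eif4g3, and the cap-binding factor gene Eif4e exceeded Eif4ebp2 (log2 2.26 ± 0.36, per kilobase 1.53 ± 0.39). Mknk2 was 1.58-fold above Mknk1, and Eif4ebp2 and Eif4ebp1 were not separated (−0.10 ± 0.36; limma adjusted p = 0.39). Of the stress response genes, the chaperone gene Hspa5 (722 ± 90.9 CPM), Asns (175 ± 7.11 CPM) and Herpud1 (92.1 ± 6.01 CPM) were highest, and Atf4, at 34.0 ± 6.76 CPM, was 2.90-fold above Ddit3 but 1.46-fold per kilobase. Among the kinases that phosphorylate eIF2, Eif2ak2 was 1.83-fold above Eif2ak4 and 4.79-fold per kilobase, while Eif2ak1 and Eif2ak3 were not separated as CPM (−0.15 ± 0.13; limma adjusted p = 0.1) but were per kilobase (0.64 ± 0.13; limma adjusted p = 3.6e-06). Across all 45 pairs, 40 passed an adjusted p of 0.05 in limma, 29 with the first gene higher and 11 with the second. Per kilobase 43 passed, and Nefh over Prph was the only pair called both ways with opposite direction.

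Ribosomal protein genes had a median of 41.0 ± 4.03 CPM with 82 of 86 detected, lower than nuclear genes of oxidative phosphorylation at 90.3 ± 14.3 CPM with 90 of 98 detected. The difference was −1.11 ± 0.13 on the log2 scale and −1.24 ± 0.12 per kilobase. The ribosomal protein level is uncertain, since 23 of 81 of these genes were less than 25% unique and had a median of 69.4 CPM per kilobase, against 104 for the 8 genes over 80% unique. Rpl4 at 263 ± 17.6 CPM and the ATP synthase gene Atp5b at 1283 ± 60.5 CPM led these lists. The undetected members were paralogs or pseudogenes for the most part, among them Rpl10l, Rpl39l, Cox7b2 and Cox8c. Of the 13 mitochondrially encoded mRNAs 12 were detected, with mt-Cytb at 1592 ± 601 CPM, mt-Nd5 at 1091 ± 446 CPM and mt-Co1 at 945 ± 267 CPM, and mt-Co2 at 0.240 ± 0.0730 CPM was not. The coding sequence of mt-Co2 had a unique share near 0.

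Other groups fixed in advance were mostly low. The taxane transporter Abcb1a, which encodes P-glycoprotein, was at 80.7 ± 10.5 CPM and Abcc1 at 40.1 ± 1.68 CPM, and the hepatic uptake transporter Slco1b2 was not detected. The p53 target Cdkn1a was at 70.2 ± 11.6 CPM and Phlda3 at 29.8 ± 6.05 CPM, with Gdf15 not detected and a list median −0.16 ± 0.14 from the median gene, or 0.35 ± 0.10 per kilobase. All 8 proliferation genes were detected, led by Mki67 at 52.0 ± 5.94 CPM and Top2a at 31.3 ± 4.14 CPM, and their median was −2.59 ± 0.22 from that of macrophage genes. Of 8 immediate early genes 6 were detected, with Nr4a1 at 52.5 ± 9.38 CPM, Egr1 at 32.2 ± 8.34 CPM and Fos at 9.14 ± 2.34 CPM, and Fosb and Npas4 were not. The noncoding RNAs were Rmrp at 2245 ± 693 CPM, Malat1 at 182 ± 51.0 CPM, Rn7sk at 20.1 ± 9.80 CPM, Snhg11 at 19.2 ± 2.77 CPM, Meg3 at 13.2 ± 2.66 CPM, Neat1 at 12.6 ± 4.51 CPM and Miat at 1.93 ± 0.526 CPM.

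Among the fixed lists, those of skeletal muscle, fat and mitochondrial genes held the largest shares of genes that differed between libraries. Of 15728 genes tested, 242 varied between libraries beyond genes of the same level at an adjusted p of 0.05 in limma's F test, and 101 of these were protein coding. All 8 skeletal muscle genes were among them (Fisher's exact adjusted p = 1.1e-13), and all 8 also passed when adjusted over the list alone. Each of the 8 was highest in replicate 1. Acta1, the muscle actin, stood at 1571, 454, 828 and 485 CPM in replicates 1 to 4, and the myosin gene Myh4 at 1245, 173, 546 and 372 CPM. The 95% Wilson interval of Acta1 was 1539 to 1603 CPM in replicate 1 and 441 to 468 CPM in replicate 2. Without replicate 1, 3 of the 8 were called. Of 5 adipocyte genes 3 were called, Car3, Cfd and Fabp4 (Fisher's exact adjusted p = 4.8e-04), and 5 when adjusted over the list alone; without replicate 2 or without replicate 3 the number called was 0. Car3 stood at 479, 168, 367 and 202 CPM, which ranks the libraries in the same order as Acta1. Whether its reads came from fat or from muscle was not tested. Of 12 mitochondrially encoded mRNAs tested 9 were called (Fisher's exact adjusted p = 1.8e-13), and 12 when adjusted over the list alone, and without replicate 3 the number was 0. Fisher's exact test counts genes as independent, whereas genes of a list that shift together in the same library are not. These Fisher p-values therefore overstate the evidence. Without the robust prior the variance test called 12 genes, 0 of them from these 3 lists. The mt-Cytb values were 1041, 1611, 2423 and 1295 CPM.

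**Figure D3:**
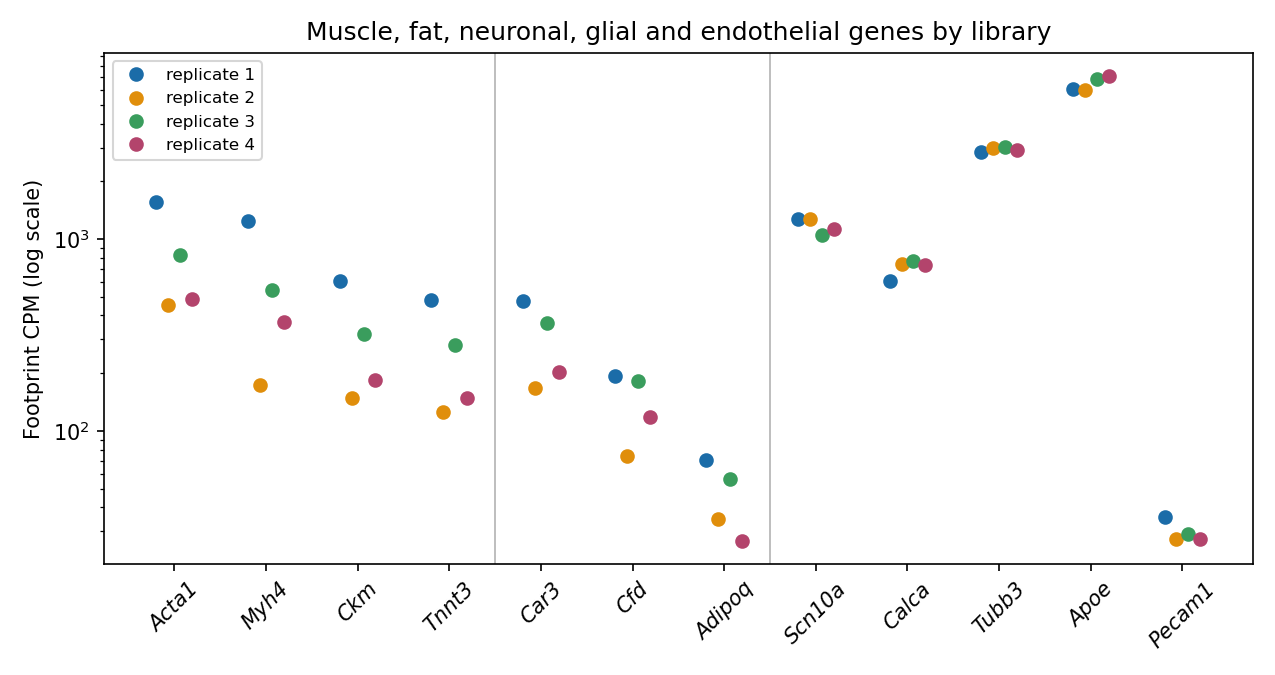
Footprint level (CPM, log axis) of 12 genes, 1 point per library, with muscle genes on the left and genes of the adipocyte list in the middle. Neuronal, glial and endothelial genes are on the right. Acta1 spans 454 to 1571 CPM, with replicate 1 highest, whereas Tubb3 has 2939 ± 81.0 CPM over the same libraries.

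No gene of the nociceptor, ion channel, glial, macrophage or neurofilament lists was among the 242. Of 90 nuclear oxidative phosphorylation genes tested 1 was called, Cox6a2, the heart and muscle form of a cytochrome oxidase subunit, which was named after its values were seen. Adjustment over the list alone was looser and not planned. It passed 5 of 12 myelinating Schwann cell genes, 4 of 7 fibroblast genes and 3 of 6 mural cell genes. Also passing were 3 of 8 noncoding genes and 2 of 90 nuclear oxidative phosphorylation genes. In addition, 1 gene each passed of 7 myelinated afferent, 14 tubulin, 6 repair Schwann cell and 6 erythroid genes tested. Among the 20 genes with the smallest p, Mbtd1 stood at 15.7, 341, 661 and 1210.0 CPM in replicates 1 to 4, Prim1 at 22.5, 271, 590.4 and 1077 CPM, Fibcd1 at 12.4, 114, 154 and 188 CPM, Dact3 at 16.7, 29.8, 189 and 182 CPM and 4930522H14Rik at 0.174, 15.2, 407 and 58.7 CPM, with replicate 1 lowest in each. Ahnak2 was lowest in replicate 3, at 404, 247, 9.98 and 462 CPM, and Ppl lowest in replicate 2, at 11.9, 6.37, 86.2 and 94.6 CPM. Tbc1d21 and Stag3 were highest in replicate 4, at 38.9 and 70.9 CPM. Of noncoding genes, 4921534H16Rik, Gm25732 and Gm23246 were lowest in replicate 1 and Gm25587 in replicate 4. Gm15584 and the Y RNA gene Rny1 were highest in replicate 1, Gm22567, 2900060B14Rik and AC122546.1 in replicate 2, and the microRNA gene Mirlet7b in replicate 4. The largest deviation was that of mt-Rnr2 in replicate 3. The number of genes called fell to 106 without replicate 3 and 148 without replicate 2.

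**Figure D4:**
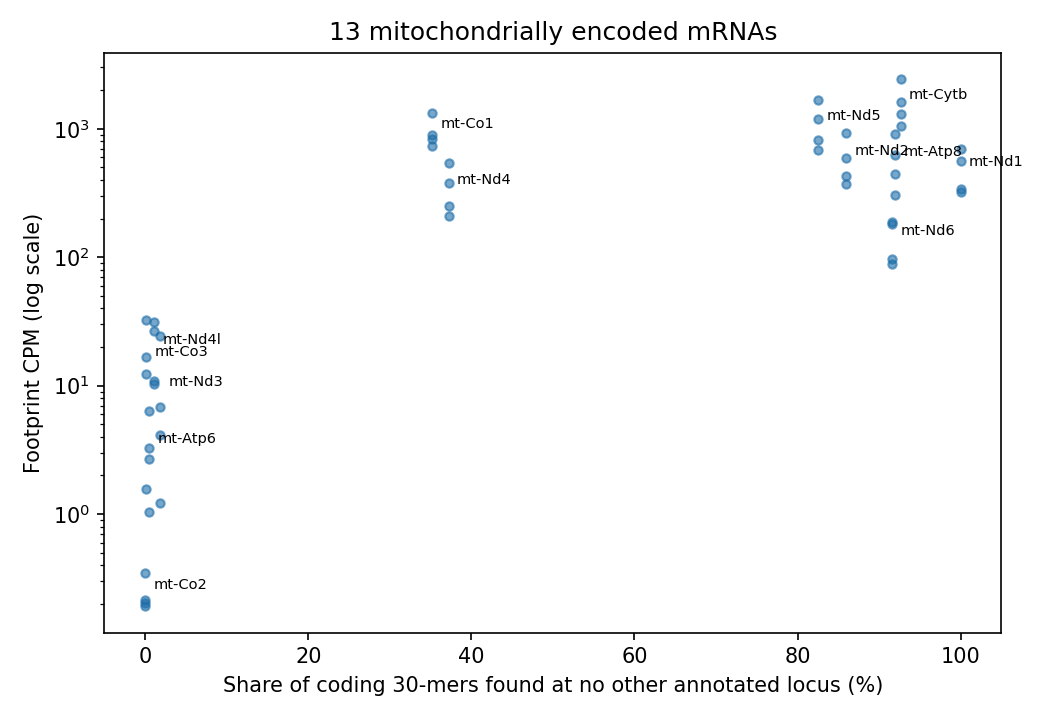
Footprint level (CPM, log axis) of the 13 mitochondrially encoded mRNAs against the share of coding 30-nt words found at no other annotated gene (percent), 1 point per library. The 5 genes near 0% had means of at most 19.7 CPM, and the genes above 80% of at least 138 CPM.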

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

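Of 122 values examined for a library far from the other 3, 4 stood apart, and chance gives about 1 in 20. No explanation was tested for any of them. Among them, the log2 ratio of the tubulin genes Tubb4b over Tubb4a was −0.75 in replicate 3, against −0.90 to −0.88 in the others. Map1b stood at 12696 CPM in replicate 2, above 9989 to 10425 CPM elsewhere. Prune2 stood at 3693 CPM in replicate 3, below 4063 to 4073 CPM elsewhere.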

How the results depend on the processing

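The alternatives with coding length, protein-coding genes only and a unique share of at least 90% were chosen after the data were examined; the rest were planned. Detected genes, the number of lists above the median gene, the number of list pairs and the number of gene pairs called stayed within 1.5 times under all alternatives run. Gene pairs called ranged from 31, in the smaller set of 90% unique pairs, to 43 per kilobase, where all 45 pairs were tested.

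The 242 variable genes became 106 to 205 when 1 library was left out, 757 without a level filter, 135 among protein-coding genes, and 12 without the robust prior, all 12 among the 242. The mean r between libraries moved from 0.979 to 0.969 with a pseudocount of 0.1 and to 0.973 at a mean of at least 5 CPM.

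Per kilobase of coding sequence, the log2 values that changed sign included C-fibre mechanoreceptor genes to 0.75, calcium channels −0.14, neuropeptides 1.40, p53 targets 0.35, noncoding 2.21 (from Snhg11, the member with a coding length), peptidergic against myelinated afferents 0.82, myelinating Schwann cell against satellite glia 0.34, Nefh over Prph −0.19, Mapt over Map2 1.25 and Eif2ak1 over Eif2ak3 0.64. With means over members, noncoding genes turned to 0.49, peptidergic against myelinated afferents to 0.094, and Schwann cell against satellite glia to 0.56. Neuropeptides turned to 0.59 over members with a mean of at least 1 CPM, and itch neuron genes to −0.20 over members at least 90% unique. Leaving out 1 library, Mapt over Map2 ranged from −0.093 to 0.046 and Eif4ebp2 over Eif4ebp1 from −0.22 to 0.060. Length enters the per kilobase values by construction; for the other changes the cause was not tested.

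Rescaling gives no value for the mitochondrial list or for pairs holding one of the 20 highest genes, and the Y-linked list has no member at a mean of 1 CPM. No paired analysis was possible because the labels give 1 group. With 4 libraries, the sign-flip tests of list levels and list pairs cannot pass 0.05, and at 1 to 5 CPM the median coefficient of variation was 26.3%.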

Other observations

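Small noncoding RNAs made up a large part of the genes that differed between libraries. Of 180 snoRNA genes tested 36 were called variable, as were 27 of 84 snRNA genes and 23 of 72 microRNA genes, against 101 of 14113 protein-coding genes. These counts by type were taken after the data were examined. Lars2, the second highest mRNA by mean level, was also called (limma adjusted p = 0.0074), at 4288, 8345, 10505 and 14534 CPM in replicates 1 to 4. So was Gm24601, at 2512, 1821, 4848 and 5809 CPM (limma adjusted p = 0.006).

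Among the tests that follow, those on the neuron share, on unique shares, on coding length and on mt-Rnr2 were chosen only after their values had been seen, and the bound for the neuron share was changed afterwards from a difference of 1 to the SD over genes. No biological explanation was tested, since the design holds 1 group.

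Muscle genes were highest in replicate 1, where their list lay 1.51 above the other libraries on the log2 scale, and the adipocyte list lay 0.84, the fibroblast list 0.54 and the mural cell list 0.43 above them and the mitochondrially encoded list 0.79 below, although the adipocyte median was highest in replicate 3 (172 against 145 CPM in replicate 1). The lower depth of replicate 1 was argued against for muscle, since the highest shift among 10000 lists matched on level was 0.38. A lower share of neurons would raise all other cell types alike. For muscle it was argued against as the whole cause, since the muscle shift exceeded that of satellite glia by 1.51 (SD over genes 0.32). Satellite glia had the lowest shift of the 6 non-neuronal lists compared. Muscle also exceeded fibroblasts by 0.97 (SD 0.34). For fat no conclusion was drawn, since its excess over satellite glia was 0.83 (SD 0.29), below the first bound of 1. Fat exceeded fibroblasts by no more than the SD (0.29 against 0.31). Attached skeletal muscle carried along in varying amounts stays open as a candidate explanation: a second muscle list, which shares no gene with the first, shifted by 1.47, with 14 of 15 genes highest in replicate 1. Its most abundant genes were Ttn at 1136 ± 790.1 CPM and Atp2a1 at 669.9 ± 456 CPM, and how many of its genes ganglion cells make themselves is not known from these libraries.

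Some transcripts that cells use heavily read low, among them mt-Co2, mt-Atp6, mt-Nd3, mt-Co3 and mt-Nd4l. Short coding sequences were argued against, since mt-Atp8 is shorter than each of these and stood at 570.1 CPM. Reads shared with copies elsewhere may have been left out. Across the 13 mRNAs the mean level rose with the unique share (Spearman's rho 0.73, Pearson's r 0.64, permutation p = 0.0061). The mRNAs named above, all with unique shares near 0, were picked for their low levels, so this p-value is not independent support. Among the other mRNAs the level did not simply follow the share. The means were 945 CPM for mt-Co1 (35.2% unique), 138 CPM for mt-Nd6 (91.6%) and 1592 CPM for mt-Cytb (92.6%). Across 81 ribosomal protein genes CPM per kilobase rose with the unique share as well (rho 0.29, r 0.25, permutation p = 0.0080; rho 0.33 without the 2 most extreme genes), and genes are not independent. For mt-Rnr2, listed at 0 in replicate 3, better removal of mitochondrial ribosomal RNA was argued against, since mt-Rnr1 was not lower there. It was 1652 CPM higher than in any other library. Losing mt-Rnr2 reads raises the CPM of all other genes, so part or all of this margin may come from that. A locus skipped for holding too many reads could account for the 0. The mt-Rnr1 reads of replicate 3 and the lowest ratio elsewhere predict 859886 mt-Rnr2 reads, above the 568766 of the fullest other library. The highest ratio predicts 1901566.

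Granulocyte and erythroid genes were present in ganglia with few lymphocyte genes. Bone marrow carried along is a candidate source, since 15 of 15 marrow precursor genes were detected in all 4 libraries. They were led by Ltf at 146 ± 8.82 CPM, Sptb at 131 ± 19.5 CPM, Prg2 at 120.0 ± 50.4 CPM and Mpo at 101 ± 16.6 CPM. The list median was 15.5 CPM, and 13549 protein-coding genes were detected by the same rule, so detection alone is weak support. Sptb encodes a spectrin also made outside the blood lineage, and no gene of this list is in another list. Blood left in vessels cannot be told apart from it, since the precursor median exceeded that of 6 mature neutrophil genes, of which 5 were detected, by only 0.61 on the log2 scale. Mmp9, at 79.4 ± 10.8 CPM, was the highest of the mature genes.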
